A study of Mus musculus with 4 samples.

How the data were processed

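The data are single-cell RNA profiles of immune cells from the ischemic brain hemisphere of C57/BL6 mice. The mice underwent transient middle cerebral artery occlusion (tMCAO), a stroke model in which an artery of the brain is blocked and then reopened. Per the labels, cells with high CD45, a surface protein of leukocytes, were sorted by flow cytometry 5 or 14 days later and processed with 10x Genomics Single Cell 3' v2 reagents. Each day has 2 libraries, given as replicates 1 and 2, so 4 libraries in all. The labels do not say whether a library holds the cells of 1 mouse or of several, so every p-value measures the spread between libraries and nothing finer.

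The authors deposited raw UMI counts (counts of unique molecular identifiers, the tags that mark single RNA molecules) per gene and cell barcode, with no normalization. Per the submitters' processing notes, Cell Ranger 3.0.1 and Seurat 2.3.4 were used with the mouse genome build GRCm38 (mm10). The deposited files list 31053 genes and hold only barcodes already called as cells. Per the file headers, the day 5 matrices were written by software version 3.0.1. The header of the day 14 matrices is empty, in an older layout, so any difference in upstream processing runs along the same line as the difference in days. The annotation release is not stated. Gene symbols and identifiers are those of the deposited files.

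The libraries hold 2543 and 3486 barcodes on day 5 and 2583 and 2313 on day 14. Total UMI counts are 10730791 and 13610119 on day 5 and 9288054 and 10759904 on day 14. The lowest UMI count of any barcode is 500 and 505 in the day 5 libraries and 1180 and 1317 in the day 14 libraries. All 4 libraries carry Y-linked transcripts and almost no Xist, so none stood apart by sex. The difference between the libraries of 1 day, as chi-square per gene, was 16.4 and 19.9, which leaves no sign that 2 libraries hold the same cells.

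Barcodes with 200 or more genes detected were clustered together without batch correction. Counts were log-normalized, and 2000 variable genes were chosen without T cell receptor and immunoglobulin segments and without mitochondrially encoded genes, the last an addition made after the data were seen. Then 30 principal components, 20 nearest neighbours and Leiden clustering at resolution 1 gave 21 clusters (scanpy 1.11.5, igraph 0.11.9, scikit-learn 1.9.0, Python 3.11.15). Clusters took the class whose fixed markers scored highest. A class needed 3 or more markers at 50 CPM, the UMI count scaled to a common total, and at least 1 marker among the 20 leading genes of the cluster. These numerical limits on cluster names were not among the choices fixed beforehand. All 176 listed markers were found. In all, 3 barcodes had under 200 genes and 81 had over 10% mitochondrial UMIs, and these were left out.

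Scrublet, run within each library through scanpy, called only 11 of 10925 barcodes doublets (0.101%), too few for droplet libraries of this size. The handling of doublets was therefore extended after the data were seen. A lymphocyte was left out as a mixed cell when over 2% of its UMIs came from 7 phagocyte genes (Apoe, C1qa, C1qb, C1qc, Lyz2, Ctsb, Cst3). Any other cell was left out at 3 or more UMIs from 4 T cell or 3 B cell genes, and lymphocytes at 3 or more UMIs of the other lymphocyte kind. This removed 648 cells, 81 and 157 on day 5 and 269 and 141 on day 14. A cluster with a Scrublet score over 0.1 in over 50% of its cells was left unnamed. Results with the Scrublet calls alone, the handling first intended, are given as an alternative. The 10183 cells used number 2423 and 3288 on day 5 and 2308 and 2164 on day 14.

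UMI counts were summed per library and class, since cells are not replicates. A class was tested for genes with 20 or more cells in every library, which 8 classes had. Day 14 was set against day 5 with edgeR 4.0.16 (quasi-likelihood F test, TMM normalization, filterByExpr, day as the only term) in R 4.3.3. Adjusted p-values are Benjamini-Hochberg values over the genes tested in a class, with a threshold of 0.05, and are two-sided. Fold changes are log2 values of day 14 over day 5 with the standard error (SE) from the F statistic. CPM values given beside them use the TMM library sizes. Shares of classes were compared by a two-sided exact permutation test, and intervals on shares are exact binomial ones at 95%. Those intervals, and the Poisson intervals on counts, cover counting error only.

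T cells with 1 or more Foxp3 UMIs were compared with T cells that had no Foxp3 UMI, 1 or more Cd4 UMIs and no Cd8a or Cd8b1 UMI, with edgeR and the library as a block. Foxp3, Cd4, Cd8a and Cd8b1 define these sets and are not results. The difference of the day effect between microglia and monocytes or macrophages was tested with edgeR as a class by day interaction, again with the library as a block. Each class was also tested for 24 gene lists with limma 3.58.1 (camera, preset inter-gene correlation of 0.01, Benjamini-Hochberg over all lists and classes), beside camera with an estimated correlation and fry. Preset correlation assumes nearly independent genes, and the estimated one rests on 2 residual degrees of freedom, so the first is liberal and the second is conservative.

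The genes named for a class are those with the largest absolute fold change among genes with an adjusted p under 0.05, a mean of 50 CPM or more in the higher day and both libraries of 1 day above both of the other. They are 10 per direction for T cells, monocytes or macrophages, microglia and the comparison of Foxp3-positive with other CD4 T cells, and 5 per direction for the other classes and the interaction. Gene models without a name, ribosomal protein genes, mitochondrial genes, Xist, Y-linked genes and antigen receptor segments were not named. For Foxp3-positive T cells, all libraries that gave an order had to go one way, and a library with equal or no counts in both sets gave none. Members of a gene list that passed are given as examples of it, at most 4 per list and class. Spp1 and Foxp3 are given where they were tested, and of the receptors of osteopontin those that passed, with a count and range of the others. The text prints a part of the named genes. A fold change against libraries that are all at 0 is given as a lower bound, from 3 counts over the libraries of that day.

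The classes, their markers, the gene lists, the tests, the threshold on adjusted p, the rule for named genes and most alternatives were fixed before the data were examined. The alternatives were DESeq2 1.42.0, RLE size factors, no filter on low counts, the replicate number as a block, leaving out each library, a mitochondrial limit of 5%, keeping doublets, 1000 UMIs per cell, Leiden resolution 2, thinning to equal depth, and other definitions of Foxp3-positive and comparison cells. Chosen after the data were seen were the Scrublet calls alone, the highest library floor for all cells, leaving out high doublet scores, counting cluster 2 as microglia, leaving out genes with shared 3' ends, and the day 14 libraries alone. So were keeping doublets in the gene comparison of Foxp3-positive cells, and leaving out of the T cells a sub-cluster with 3 or more NK or innate markers and no T cell marker among its 20 leading genes. For shared 3' ends, every 30-base window of the last 300 bases of each annotated transcript (GENCODE M21 on GRCm38) was searched in the transcripts of other genes, and a gene with 50% or more shared windows counted as shared.

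The edgeR steps were tested on simulated counts drawn from the means and sizes of the same sums, with 100 genes changed 2-fold and 100 changed 4-fold. For monocytes or macrophages 62% of the 2-fold and 93% of the 4-fold changes were recovered among 8871 genes, for microglia 36% and 82% among 7780, and for dendritic cells 74% and 95% among 8941. For T cells 17% and 54% were recovered among 5244 genes, for NK cells 23% and 80% among 5195, for neutrophils 29% and 79% among 3878, for plasmacytoid dendritic cells 33% and 84% among 2903, and for B cells 38% and 87% among 2180. For Foxp3-positive against other CD4 T cells 60% and 92% were recovered among 1084 genes, and for the interaction 20% and 60% among 9692. False calls made up between 0.917% of calls (neutrophils) and 7.19% (monocytes or macrophages, 12 of 167), the latter above 5%. A list moved in a simulation was called, and 0 of 23 other lists were. Genes were drawn independently there, so the simulation could not show false list calls that come from correlated genes. Classes with under 20 cells in a library (gamma delta T or innate lymphoid cells and border-associated macrophages) and 3 unnamed clusters were left out of the gene tests.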

Results

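Single-cell RNA profiles were collected from leukocytes of the ischemic mouse hemisphere 5 and 14 days after tMCAO, with 2 libraries per day. After filtering, 10183 cells formed 21 clusters, which were assigned to 10 cell classes and 3 unnamed clusters. The libraries kept 2423 and 3288 cells on day 5 and 2308 and 2164 cells on day 14. The median UMI count per barcode was 3502 and 3023.5 on day 5 and 2882 and 4230 on day 14. Values after ± are SD for shares and CPM and SE for log2 fold changes, and n = 2 libraries per day except where another n is given.

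The first question was how the immune cells of the injured hemisphere differed between the acute and the later day. T cells made up 1.41% ± 0.104 of cells on day 5 and 17.8% ± 6.43 on day 14. The rule for mixed cells took a larger part of the T cell clusters on day 5 than on day 14. It removed 25 of 61 and 48 of 92 cells on day 5 (41.0% and 52.2%). On day 14 it removed 109 of 624 and 42 of 328 (17.5% and 12.8%), so the size of the T cell difference depends on that rule. Gamma delta T or innate lymphoid cells rose from 0.743% ± 0.233 to 7.97% ± 4.60, NK cells from 4.39% ± 0.619 to 12.6% ± 0.0276 and B cells from 2.38% ± 0.158 to 6.60% ± 3.78. Microglia, the resident macrophages of the brain, went from 34.5% ± 5.44 to 3.80% ± 1.25. Border-associated macrophages went from 4.49% ± 2.38 to 0.650% ± 0.0612 and neutrophils from 8.37% ± 0.307 to 3.59% ± 0.374. In these 7 classes both libraries of 1 day lay above both of the other, and the two-sided exact permutation p was 0.333, the smallest that 2 against 2 libraries allow. Monocytes or macrophages (18.6% ± 3.85 and 21.4% ± 10.8), dendritic cells (16.1% ± 3.67 and 18.5% ± 7.17) and plasmacytoid dendritic cells (1.36% ± 0.352 and 1.75% ± 0.774) overlapped between days. Without day 14 replicate 2 the difference was -4.79 percentage points for monocytes or macrophages and -2.62 for dendritic cells, without day 5 replicate 2 it was -0.152 for dendritic cells, and without day 14 replicate 1 it was -0.162 for plasmacytoid dendritic cells. The B cell difference of 4.22 points was 1.55 without day 14 replicate 1 and 6.89 without day 14 replicate 2, and that of gamma delta T or innate lymphoid cells, 7.22, was 3.97 without day 14 replicate 1. The difference of -3.84 in border-associated macrophages was -2.16 without day 5 replicate 2. Of the T cells 178 formed a sub-cluster led by Klra7, Klra1, Xcl1, Klre1, Trdc and Fcer1g, with no T cell marker among its 20 leading genes. A Cd3d, Cd3e or Cd3g UMI was found in 95.5% of them, Trac in 55.1% and Trdc in 22.5%, so part of them may belong to another class; without them the T cell difference was 12.8 points.

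**Figure D1:**
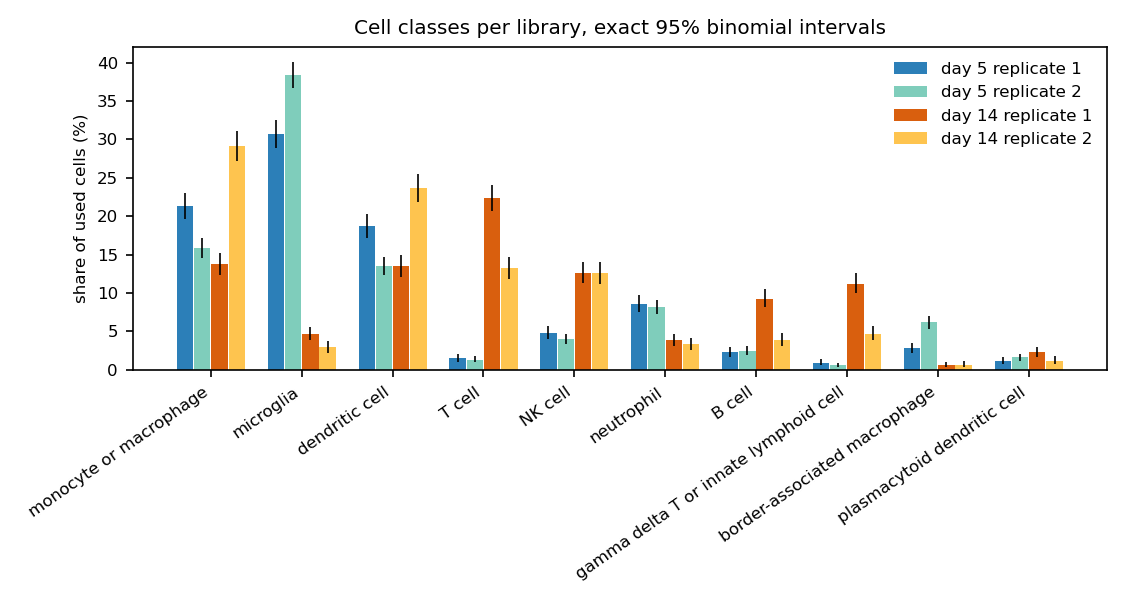
Share of each cell class among the cells used, in percent, with 1 bar per library and its exact binomial interval at 95%. T cells lay at 1.49% and 1.34% on day 5 and at 22.3% and 13.2% on day 14, and microglia at 30.7% and 38.4% on day 5 and at 4.68% and 2.91% on day 14.

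Regulatory T cells, which express the transcription factor Foxp3, are named in the series title. A Foxp3 UMI was found in 4 of 80 T cells on day 5 and 70 of 801 on day 14, a mean share of 5.05% ± 0.714 and 8.74% ± 0.00240. The difference of 3.69 percentage points had an exact permutation p of 0.333, the smallest possible, and the exact binomial intervals at 95% overlapped, from 0.680% to 18.7% and 0.555% to 15.5% on day 5 against 6.44% to 11.5% and 5.74% to 12.6% on day 14. After thinning to 1000 UMIs per cell the shares were 4.08% and 4.58%, so a difference was not detectable at equal depth. T cells of sub-clusters led by regulatory markers made up 11.2% on day 5 and 11.8% on day 14. In all classes other than T and gamma delta T or innate lymphoid cells, 0.0310% and 0.178% of cells had a Foxp3 UMI. In NK cells the day 14 share was 0.184%, at median UMI counts of 2103 and 2965 beside 2259 and 2516 in T cells. The Foxp3 level within T cells did not pass between days, at 0.74 ± 0.60 (adjusted p 0.780).

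Foxp3-positive T cells were set against other CD4 T cells of the same libraries. Of 1082 genes tested, 53 differed, 31 higher and 22 lower, and 176 had an unadjusted p under 0.05. Il2ra, the alpha chain of the interleukin 2 receptor, was higher by 1.95 ± 0.38 (adjusted p 0.00243), at 568 against 127 CPM on day 14, and was higher in all 4 libraries. The proliferation genes Birc5 (4.84 ± 0.72), Hist1h2ap (4.08 ± 0.41), Stmn1 (2.94 ± 0.47) and Cks1b (2.42 ± 0.52) were also higher. Birc5 and Hist1h2ap gave an order in only 2 libraries. On day 14 the Foxp3-positive sets held 211955 UMIs in 45 cells and 139700 in 25. The other CD4 sets held 173676 in 72 cells and 87792 in 29. Cells were picked by a Foxp3 UMI and were not compared at equal depth per cell, so depth is not separated from these proliferation values. Of the list for regulatory T cell effector and tissue repair, Klrg1 (2.54 ± 0.64, adjusted p 0.0204) and the growth factor gene Areg (1.28 ± 0.36, adjusted p 0.0382) were higher (Klrg1 in 3 libraries, with 1 lower) and the enkephalin gene Penk was lower (-5.20 ± 0.72, adjusted p 9.94e-05; lower in 2 libraries and higher in 1). With 2 genes up and 1 down of 12 (5 adjusted over the list alone) camera did not call that list (adjusted p 0.883). Ikzf2, which is not in it (1.13 ± 0.34), had an adjusted p of 0.0525. Lower were the granule gene Nkg7 (-2.32 ± 0.34), the chemokine receptor Cxcr3 (-1.42 ± 0.39), and Tnfsf8 (-3.47 ± 0.74). The chemokine receptor Cxcr6 was lower by -2.03 ± 0.52, with an adjusted p of 0.0717 without day 5 replicate 2. Among the lists, cell cycle was higher, with 5 of 5 genes up (5 adjusted over the list alone; camera adjusted p 0.00484, and adjusted p = 0.677 with an estimated correlation). Tissue resident T cell was lower, with 2 of 6 genes down (2 adjusted over the list alone; 0.0129, and adjusted p = 0.677 with an estimated correlation). Day 5 gave only 2 and 2 Foxp3-positive cells, so the comparison rests on the 45 and 25 of day 14, and the day 14 libraries alone gave 336 genes. Without day 14 replicate 1 edgeR called 1 of 175 tested genes (7 at an unadjusted p under 0.05), without day 14 replicate 2 it called 0 of 173 (2 at an unadjusted p under 0.05), and without day 5 replicate 1 it called 181; DESeq2 with all libraries called 7. All 20 named genes of this comparison thus have no call without 1 of the day 14 libraries, 18 of them because they were no longer tested.

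Osteopontin, the product of Spp1 (ENSMUSG00000029304), is the other molecule in the series title, and its RNA was compared by class. In monocytes or macrophages Spp1 rose by 1.79 ± 0.25 from day 5 to day 14 (adjusted p 5.83e-04), from 2637 to 9133 CPM. In microglia it was 5879 CPM on day 5 and 10693 on day 14, a change of 0.86 ± 0.36 that did not pass (adjusted p 0.215). Spp1 was lower on day 14 in dendritic cells (-1.15 ± 0.20, adjusted p 0.00162, adjusted p 0.116 in DESeq2, and -0.60 with high doublet scores left out). It was also lower in neutrophils (-0.77 ± 0.20, adjusted p 0.0266), where it was -0.072 with high doublet scores left out and -0.90 and short of the threshold at Leiden resolution 2. The thinned share with an Spp1 UMI was 22.5% and 22.9% in dendritic cells and, against the fall, 32.2% and 45.9% in neutrophils. In monocytes or macrophages that share was 37.7% on day 5 and 38.2% on day 14, and the libraries of the days overlapped. The rise of Spp1 in CPM there thus came without a clearly larger share of cells with an Spp1 UMI at equal depth. Spp1 per UMI of Apoe, C1qa, C1qb and C1qc overlapped between days. It was 0.126 and 0.0982 against 0.0822 and 0.149 in dendritic cells and 0.104 and 0.0792 against 0.0616 and 0.126 in neutrophils. RNA from other phagocytes thus stays open for both falls. The Spp1 change in B cells (1.45 ± 0.28, adjusted p 0.0551), T cells (0.50 ± 0.41, 0.784), NK cells (0.33 ± 0.25, 0.620) and plasmacytoid dendritic cells (-0.41 ± 0.41, 0.751) did not pass. With Scrublet calls alone Spp1 was -2.10 in B cells (adjusted p 9.94e-04) and -0.33 in NK cells, so the direction in these classes depends on the handling of mixed cells. The highest Spp1 levels lay in unnamed cluster 6, led by Cst7, Spp1, Apoc1, Fabp5 and Gpnmb, at 12325 and 9901 CPM on day 5 and 12380 and 28455 on day 14. Microglia was the best-scoring type of that cluster, but no microglial marker was among its leading genes, so it is not in the microglial values. Foxp3-positive T cells of day 14 held 160 CPM (95% counting interval 111 to 224) and 243 CPM (169 to 340), beside 211 and 277 in B cells and 141 and 234 in NK cells of the same libraries. Foxp3-positive T cells were lower in Spp1 than other CD4 T cells by an amount that did not pass (-0.99 ± 0.31, adjusted p 0.0738).

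Among receptors of osteopontin, Itgb5 was lower on day 14 in dendritic cells (-2.27 ± 0.13), monocytes or macrophages (-1.08 ± 0.13), neutrophils (-1.23 ± 0.24) and plasmacytoid dendritic cells (-2.38 ± 0.44). Itga4 was higher in dendritic cells (0.79 ± 0.15) and monocytes or macrophages (0.72 ± 0.21) and lower in NK cells (-0.93 ± 0.26). Cd44 was higher in neutrophils (0.88 ± 0.23), and Itgb1 was lower in microglia (-0.72 ± 0.20). Itgb5 stood at 1060 CPM in microglia on day 5 and was lower on day 14 in all 6 classes where it was tested, so background RNA from microglia stays open. Over the classes 38 receptor values were tested, and the 29 that did not pass lay between -1.13 and 1.20. In Foxp3-positive against other CD4 T cells Itgb1 was lower (-1.94 ± 0.38, adjusted p 0.00231; lower in 3 libraries and higher in 1) and Cd44 did not pass (-0.26 ± 0.48, adjusted p 0.874). The Spp1 change depended on single libraries. In monocytes or macrophages it lay between 1.19 (without day 14 replicate 2) and 2.22 (without day 14 replicate 1), and in dendritic cells between -1.70 and -0.77 (without the same libraries), with all calls kept. In T cells it was 1.35 without day 5 replicate 1 and in NK cells 0.64 without day 14 replicate 1, without a call. Without day 14 replicate 2 it was -0.38 in microglia, -0.07 in NK cells and -0.14 in T cells; without day 14 replicate 1 it was -0.58 with an adjusted p of 0.135 in neutrophils; and without day 5 replicate 2 it was 0.61 in plasmacytoid dendritic cells. Calls appeared in microglia without day 14 replicate 1 (1.52), day 5 replicate 1 (1.28) or day 5 replicate 2 (0.58), in B cells without day 5 replicate 1 (1.62) or day 14 replicate 2 (1.42), and in plasmacytoid dendritic cells without day 5 replicate 1 (-0.91).

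**Figure D2:**
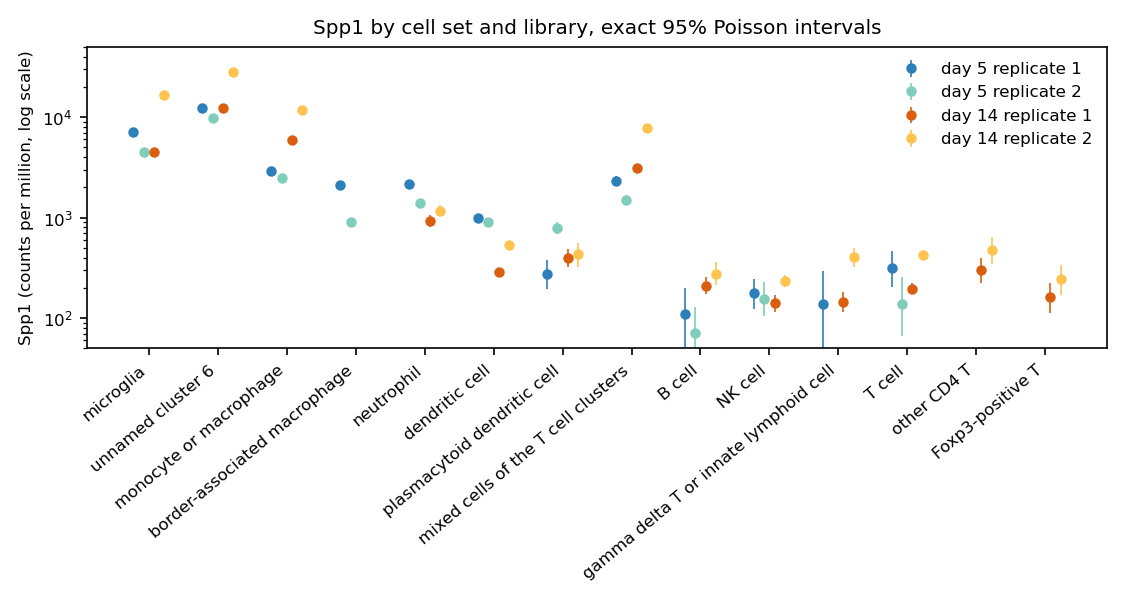
Spp1 level in CPM on a log axis by cell set, with 1 point per library and its exact Poisson interval at 95%; sets with under 20 cells in a library are not drawn for it. Monocytes or macrophages lay at 2925 and 2466 CPM on day 5 and at 5900 and 11702 on day 14, and microglia at 7123 and 4547 on day 5 and at 4476 and 16470 on day 14.

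In monocytes or macrophages, 1027 of 8871 genes differed between days, 678 higher and 349 lower on day 14. The interferon-induced genes Slfn4 (3.33 ± 0.26), Ifi213 (2.94 ± 0.16) and Ifi206 (2.85 ± 0.16) rose, with Acod1 (2.93 ± 0.33) and with Ly6a (3.50 ± 0.19), Ly6c2 (2.95 ± 0.12, 467 to 3616 CPM) and Ly6i (2.91 ± 0.18). H2-Q7 rose by 2.89 ± 0.25. Lower were Pf4 (-2.51 ± 0.18), Chil3 (-1.85 ± 0.16, 2467 to 688 CPM), Gas6 (-1.76 ± 0.18), Gdf15 (-1.83 ± 0.21), Ltc4s (-1.98 ± 0.18) and S100a8 (-2.26 ± 0.35). Tmem119 (-2.17 ± 0.18), Fcrls (-1.99 ± 0.14), Sparc (-1.85 ± 0.20) and Gpr34 (-1.76 ± 0.22), which are microglial genes, also fell. Ltc4s, Tmem119, Fcrls and Gpr34 were lower in every class where they were tested, so background RNA stays open for them. Pf4 and S100a8 are markers used here for border-associated macrophages and neutrophils. The shares of both classes were lower on day 14, so background RNA from them stays open too. The make-up of the class changed between days: cluster 13 held 6.75% of its cells on day 5 and 82.3% on day 14, while cluster 11 went from 42.7% to 3.38%. The 3' end of Ly6c2 was shared with other genes over 51.6% of its windows and that of Ly6a over 30.8%.

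In microglia, 369 of 7780 genes differed, 251 higher and 118 lower on day 14. Of the disease-associated list Itgax (2.75 ± 0.26), Cst7 (2.41 ± 0.16, 409 to 2184 CPM), Csf1 (2.12 ± 0.18) and Lpl (1.72 ± 0.18) rose. In all 7 of its 20 genes rose and 1 fell (8 and 2 adjusted over the list alone; camera adjusted p 0.00126, and adjusted p = 0.555 with an estimated correlation). Ccl5 (2.95 ± 0.18), H2-Q7 (3.26 ± 0.20), Irf7 (2.57 ± 0.29), Il1rn (2.47 ± 0.41), Ptgs2 (2.42 ± 0.34) and Il1b (1.42 ± 0.21) rose as well. In T cells Ccl5 stood at 4806 CPM on day 14, when their share was larger. Background RNA from lymphocytes thus stays open for the Ccl5 rise in microglia. Among named genes, which have 50 CPM or more, Cd5l fell most (-4.19 ± 0.45, 239 to 13.6 CPM), followed by Lgals1 (-2.60 ± 0.27), Wfdc17 (-2.44 ± 0.30), Ms4a7 (-2.40 ± 0.36) and Serpinb6a (-1.98 ± 0.38). The day 14 libraries held 108 and 63 microglia, and cluster 5 went from 52.5% to 12.9% of the class. Unnamed cluster 6, which also scored highest for microglia, held 115 and 69 cells on day 14 and is not among them. Without day 5 replicate 1 the count was 215.

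In T cells, 32 of 5244 genes differed, 27 higher and 5 lower on day 14, and 476 had an unadjusted p under 0.05. With Scrublet calls alone 712 differed, 224 higher and 488 lower, and without the innate-like sub-cluster 18 did. Plac8 (2.05 ± 0.37, 133 to 567 CPM), Ifi27l2a (1.48 ± 0.15), Ly6a (1.36 ± 0.20) and Ly6e (1.05 ± 0.15) rose. The chemokine gene Ccl5 fell (-0.86 ± 0.11, 8716 to 4806 CPM), but was 0.13 with Scrublet calls alone. With genes of shared 3' ends left out, 12 genes were called. The microglial genes Tmem119 (-3.22 ± 0.69) and Cx3cr1 (-2.31 ± 0.49) were also lower, but the first had an adjusted p of 0.706 without day 5 replicate 2 and the second of 0.256 without day 5 replicate 1. The heat shock gene Hspa1a (-2.65 ± 0.49), Dusp2 (-1.14 ± 0.22) and Ltb (0.74 ± 0.16) had adjusted p-values of up to 0.521, 0.183 and 0.353 without 1 library. The day 5 libraries held 36 and 44 T cells. Leaving out day 5 replicate 1 gave 85 genes and leaving out day 5 replicate 2 gave 69.

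**Figure D3:**
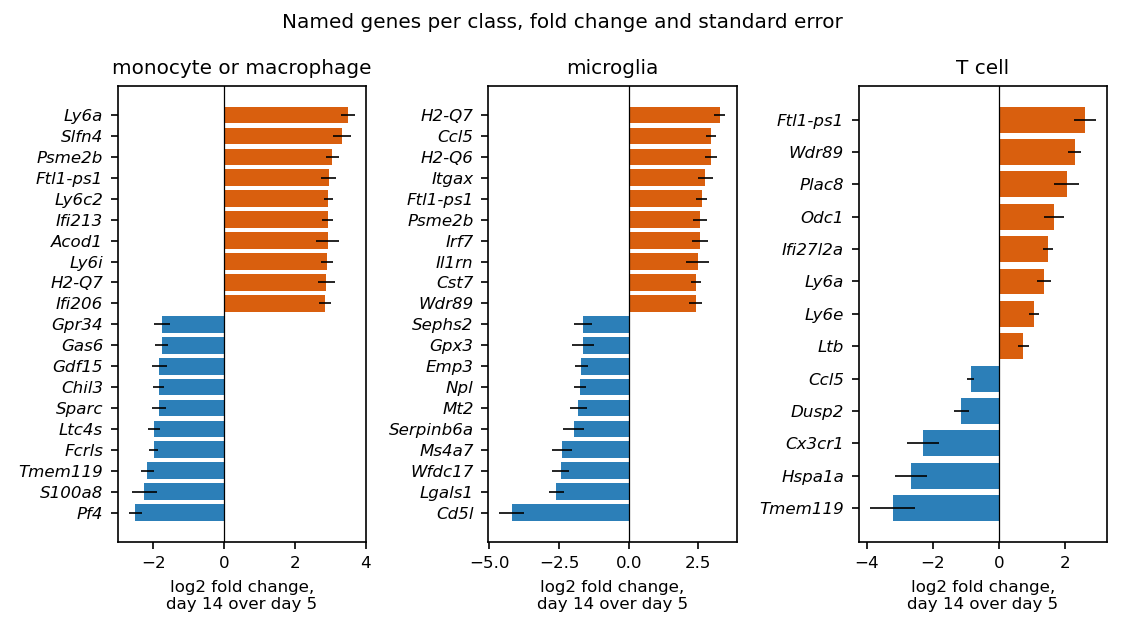
Log2 fold change of day 14 over day 5 with its SE for the named genes of monocytes or macrophages, microglia and T cells, from 2 libraries per day. Ly6a at 3.50 is the highest in monocytes or macrophages, H2-Q7 at 3.26 the highest and Cd5l at -4.19 the lowest in microglia, and Tmem119 at -3.22 the lowest in T cells. Ly6a and H2-Q7 were higher on day 14 in every class where they were tested.

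In NK cells, 307 of 5195 genes differed, 212 higher and 95 lower on day 14. Gzmc rose from 20.6 to 590 CPM (4.82 ± 0.40) and Isg20 by 3.09 ± 0.53. Gzma fell from 10929 to 2628 CPM (-2.06 ± 0.13), and Ccl5 (-2.07 ± 0.16), Klrg1 (-3.07 ± 0.39), S1pr5 (-2.78 ± 0.45) and Cma1 (-4.46 ± 0.32) fell too. The homeostatic microglia list was lower in NK cells, with 5 of 8 genes down (5 adjusted over the list alone; camera adjusted p 3.48e-04, and adjusted p = 0.553 with an estimated correlation). Without day 5 replicate 1 the count was 163, and with the highest library floor it was 95.

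In dendritic cells, 1633 of 8941 genes differed, 840 higher and 793 lower on day 14. Il12b (3.53 ± 0.40) and Tnfrsf4 (3.10 ± 0.24) rose, and Epcam (-3.34 ± 0.19) and Cd34 (-2.79 ± 0.24) fell. The microglial genes P2ry12 (-3.02 ± 0.28), Sparc (-2.75 ± 0.19) and Olfml3 (-2.68 ± 0.18) were lower as well. Ccl17 rose by 3.02 ± 0.44 and had an adjusted p of 0.0569 without day 14 replicate 2. Cluster 4 made up 68.8% of the class on day 5 and 3.16% on day 14, and cluster 16, with Cd209a, went from 15.6% to 46.2%. Cluster 10, with Xcr1, went from 8.47% to 31.4%, and cluster 20, with Ccr7, from 7.13% to 19.2%. Without day 14 replicate 2 the count was 688.

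In neutrophils, 629 of 3878 genes differed, 424 higher and 205 lower on day 14. Gdf15 (4.40 ± 0.47) and Ms4a4c (3.38 ± 0.22) rose. The granule genes Camp (-5.69 ± 1.12, 19728 ± 13624 to 375 ± 531 CPM) and Ngp (-5.66 ± 1.11) fell, with a wide spread between the libraries of each day. Pclaf was at least 14.3-fold lower on day 14, where no UMI was found. A cluster led by Camp, Ngp and Ltf held 27.3% of neutrophils on day 5 and 0.621% on day 14.

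In B cells, 35 of 2180 genes differed, 31 higher and 4 lower on day 14; with Scrublet calls alone 306 did, 151 higher and 155 lower. Scd1 (1.71 ± 0.24) and Gimap4 (1.44 ± 0.25) rose, and Vpreb3 fell from 524 to 171 CPM (-1.58 ± 0.25). Hcst (3.35 ± 0.59), Fam129c (-2.99 ± 0.41) and Btg2 (-1.20 ± 0.21) also passed, and all 8 named genes of B cells lost their call without at least 1 library. With genes of shared 3' ends left out, 1 gene was called. The B cell count was 96 without day 5 replicate 1, 89 without day 5 replicate 2, 113 without day 14 replicate 2, and 0 in edgeR without day 14 replicate 1, where 218 genes had an unadjusted p under 0.05; DESeq2 with all libraries called 105.

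In plasmacytoid dendritic cells, 101 of 2903 genes differed, 35 higher and 66 lower on day 14; with high doublet scores left out 31 did, 27 higher and 4 lower. The secretin gene Sct rose from 14.0 to 510 CPM (5.22 ± 0.87) and Usp18 by 2.49 ± 0.38. Crybb1 was at least 11.9-fold and Maf at least 7.97-fold lower on day 14, where neither had a UMI. Crybb1 is a microglial gene and was lower in all 6 classes where it was tested (called in 4). The homeostatic microglia list was lower in plasmacytoid dendritic cells, with 9 of 15 genes down (10 adjusted over the list alone; camera adjusted p 2.68e-08, and adjusted p = 0.526 with an estimated correlation), so RNA from microglia stays open for such genes. Of the 10 named genes Bhlhe41, Itgam, Pmp22 and Lrrc58 lost their call without 1 library, and Crybb1 and Maf were no longer tested without 1. The count was 188 without day 5 replicate 1 and 202 without day 14 replicate 2.

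Gene lists fixed in advance were tested in each class, 185 tests in all. Camera called 74, of which 38 were higher and 36 lower on day 14, and fry called 16. With an estimated correlation 0 were called by camera, where 9 had an unadjusted p under 0.05. The interferon response was higher on day 14 in monocytes or macrophages, with 24 of 24 genes up (24 adjusted over the list alone; Isg15 2.41 ± 0.14, Irf7 2.35 ± 0.14; camera adjusted p 2.67e-23). In neutrophils 22 of 22 of its genes rose (Zbp1 2.86 ± 0.26, Isg15 2.78 ± 0.18), in dendritic cells 21 of 24 (22 adjusted over the list alone; Irf7 1.91 ± 0.22), in microglia 19 of 23 (22), in NK cells 14 of 18 (16), in plasmacytoid dendritic cells 6 of 14 (13) and in T cells 1 of 21 (13). In B cells 0 of 7 passed in edgeR (1 adjusted over the list alone) and camera gave 0.0402. For the interferon response each of these classes had an adjusted p = 0.526 with an estimated correlation.

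Antigen presentation by MHC class I was higher on day 14 in microglia, with 9 of 12 genes up (11 adjusted over the list alone; camera adjusted p 1.47e-10, and adjusted p = 0.526 with an estimated correlation). In monocytes or macrophages 11 of 12 of its genes rose (11 adjusted over the list alone) and in dendritic cells 11 of 12 (12), both with an adjusted p = 0.526 with an estimated correlation. MHC class II split by class, a difference that was not itself tested. In neutrophils 6 of 7 genes rose (6 adjusted over the list alone; Cd74 2.31 ± 0.29; adjusted p = 0.553 with an estimated correlation) and in monocytes or macrophages 5 of 10 (7 up and 1 down adjusted over the list alone), while 7 of 10 fell in dendritic cells (1 up and 8 down adjusted over the list alone), both with an adjusted p = 0.526 with an estimated correlation. The homeostatic microglia list was lower on day 14 in 6 of the 8 classes: NK and plasmacytoid dendritic cells as given above, T cells with 2 of 10 genes down (5 adjusted over the list alone; adjusted p = 0.526 with an estimated correlation), and 3 more, with 15 of 17 genes down in dendritic cells (16 adjusted over the list alone), 12 of 16 in neutrophils (12) and 10 of 15 in monocytes or macrophages (13), each with an adjusted p = 0.526 with an estimated correlation. In microglia 2 of its 17 genes fell and camera did not call it (0.0584), nor in B cells, with 0 of 4 genes in edgeR (0.608). Heat shock and dissociation stress was higher in microglia, with 5 of 20 genes up (5 adjusted over the list alone; Ier3 0.96 ± 0.20; camera adjusted p 0.0138, and adjusted p = 0.553 with an estimated correlation). In neutrophils 6 of 19 of its genes rose (10 adjusted over the list alone; Ier3 2.12 ± 0.23; 0.00177, and adjusted p = 0.526 with an estimated correlation). It was also called higher in monocytes or macrophages, with 5 up and 2 down of 21 (9 and 2 adjusted over the list alone; 0.0320, and adjusted p = 0.580 with an estimated correlation). It was lower in B cells, with 1 of 15 down (4 adjusted over the list alone; 0.00971, and adjusted p = 0.526 with an estimated correlation), and in plasmacytoid dendritic cells, with 2 of 17 down (3; 0.0317, and adjusted p = 0.557 with an estimated correlation). The disease-associated list, called higher in microglia, was called lower in dendritic cells, with 1 gene up and 13 down of 19 (1 and 14 adjusted over the list alone), plasmacytoid dendritic cells, with 4 of 15 down (6), and NK cells, with 5 of 15 down (1 up and 7 down), each with an adjusted p = 0.526 with an estimated correlation. Where it was lower, the homeostatic microglia list was lower too, so background RNA from microglia stays open there. Cytotoxicity was lower in NK cells, with 1 gene up and 9 down of 17 (1 and 9 adjusted over the list alone; camera adjusted p 9.89e-05, and adjusted p = 0.526 with an estimated correlation) and in T cells, with 1 of 17 down (1; 0.0480). It was higher in monocytes or macrophages, with 7 up and 1 down of 10 (7 and 1), in neutrophils, with 3 of 4 up (3), and in microglia, with 2 of 6 up (2; 0.0344). In these 4 classes, too, cytotoxicity had an adjusted p = 0.526 with an estimated correlation. T and NK cells had larger shares on day 14, and the rule for mixed cells used no NK cell gene. That rule removed 0.578% and 1.51% of monocytes or macrophages on day 5 and 11.7% and 5.26% on day 14. Background RNA from lymphocytes thus stays open for the rises in cytotoxicity. The cell cycle list was higher in T cells (camera adjusted p 4.54e-05, and adjusted p = 0.526 with an estimated correlation), where 0 of 18 genes passed in edgeR and 7 did adjusted over the list alone. It was lower in microglia, with 7 of 25 down (18 adjusted over the list alone; camera adjusted p 3.74e-10), monocytes or macrophages, with 7 of 18 (11), and neutrophils, with 5 of 6 (5), each with an adjusted p = 0.526 with an estimated correlation. In dendritic cells 9 of 18 of its genes fell (11; adjusted p = 0.553 with an estimated correlation).

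Other calls of these lists, with counts adjusted over the list alone in brackets, had an adjusted p = 0.526 with an estimated correlation unless another is given. MHC class I was also higher in neutrophils, with 8 of 10 up (8), NK cells, with 5 of 11 (8), and plasmacytoid dendritic cells, with 0 of 10 in edgeR (6; camera 3.21e-04). MHC class II was higher in B cells, with 0 of 10 in edgeR (6; camera 0.00334), and lower in plasmacytoid dendritic cells, with 1 of 8 down (5; adjusted p = 0.553 with an estimated correlation). Complement and phagocytosis was lower in dendritic cells, with 1 up and 17 down of 23 (1 and 17), plasmacytoid dendritic cells, with 6 of 16 down (8), and T cells, with 0 of 11 in edgeR (6; camera 3.07e-04). It was also lower in NK cells, with 5 of 13 down (6, adjusted p = 0.553 with an estimated correlation), and in monocytes or macrophages, with 4 up and 8 down of 23 (4 and 10, adjusted p = 0.690 with an estimated correlation). The homeostatic microglia list was called lower in each of these classes too, so background RNA from microglia stays open for the falls in complement and phagocytosis. Inflammatory cytokines were higher in neutrophils, with 9 of 12 up (10), monocytes or macrophages, with 6 of 13 (6), and microglia, with 4 of 12 (8), and lower in plasmacytoid dendritic cells, with 1 of 4 down (2; adjusted p = 0.553 with an estimated correlation). The repair macrophage list was lower in dendritic cells, with 9 of 15 down (11), plasmacytoid dendritic cells, with 3 of 6 (4), and monocytes or macrophages, with 1 up and 5 down of 16 (2 and 5; adjusted p = 0.553 with an estimated correlation). Chemokines were higher in neutrophils, with 7 up and 2 down of 14 (9 and 2), and monocytes or macrophages, with 5 up and 2 down of 17 (8 and 2; adjusted p = 0.592 with an estimated correlation), and lower in plasmacytoid dendritic cells, with 3 of 8 down (6). The calls of the remaining lists are not described here.

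Whether microglia and monocytes or macrophages changed differently over time was tested as the difference of their day effects. Of 9692 genes, 218 differed, 119 with a higher effect in microglia and 99 with a lower one, and in 156 the fold changes had opposite signs. Itgax (3.61 ± 0.34, 11.9 to 81.2 CPM in microglia and 32.5 to 17.8 in monocytes or macrophages), Lpl (2.43 ± 0.23), Cxcl2 (2.23 ± 0.42), Fn1 (2.21 ± 0.30) and Bhlhe40 (2.20 ± 0.32) had the higher effect in microglia. Lgals1 (-2.32 ± 0.23), Mthfd2 (-2.09 ± 0.34) and Wfdc17 (-2.07 ± 0.29) had the lower one. Spp1 differed by -1.11 ± 0.25 (adjusted p 0.0136), with the larger rise in monocytes or macrophages. F13a1 (-2.08 ± 0.53) had an adjusted p of 0.413 without day 14 replicate 1 and 0.0673 without day 5 replicate 1, and Cd5l (-2.08 ± 0.46) had 0.176 without day 14 replicate 2. Without day 5 replicate 1 the count was 135.

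Some genes were higher in both day 14 libraries than in both day 5 libraries in every class where they were tested, with a median log2 change of 1 or more over 6 or more classes. They are said here to rise in every class, which does not ask for a call in each. Among them were genes named above for single classes. These include Ly6a (called in 7 of 8 classes), Ifi27l2a (7 of 8), Irf7 (6 of 8), H2-Q7 (5 of 8), Usp18 (6 of 7), Isg20 (5 of 7) and Ifi206 (4 of 7). Their rises are thus not particular to those classes. Ftl1-ps1 (ENSMUSG00000062382), a copy of the ferritin gene Ftl1, was called in 8 of 8 classes and rose by 2.60 ± 0.32 in T cells, 2.61 ± 0.21 in microglia and 4.50 ± 0.30 in neutrophils. Psme2b, a copy of Psme2, was called in 5 of 8 classes and rose by 3.06 ± 0.19 in monocytes or macrophages and 4.11 ± 0.19 in dendritic cells. The 3' ends of these copies were shared with other genes over 73.2% and 70.8% of their windows. Per 100 Ftl1 UMIs, Ftl1-ps1 had between 1.12 and 4.72 UMIs across classes in day 5 replicate 1, 2.44 to 4.58 in day 5 replicate 2, 20.4 to 22.1 in day 14 replicate 1 and 18.04 to 21.2 in day 14 replicate 2. Per 100 Psme2 UMIs, Psme2b had between 18.6 and 35.2 in day 14 replicate 1 and 13.04 to 29.8 in day 14 replicate 2, from as few as 9 UMIs in a class. Of 148 genes with shared ends 26 rose in every class (17.6%), against 30 of 3332 others (0.900%; Fisher's exact p 5.53e-22, across genes, which are not independent replicates).

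**Figure D4:**
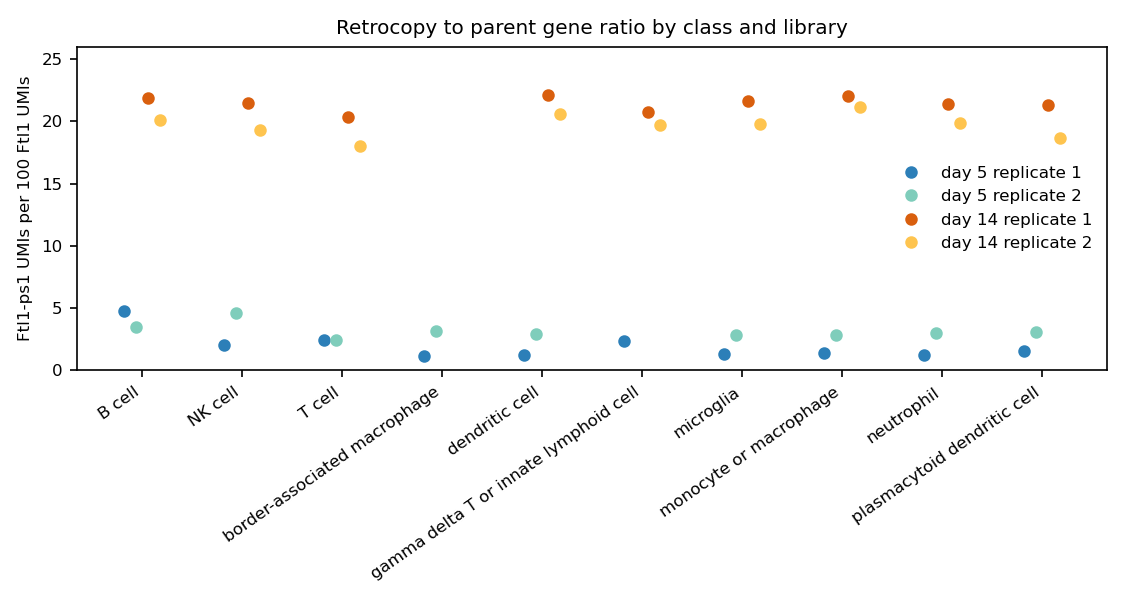
UMIs of Ftl1-ps1 per 100 UMIs of its parent gene Ftl1, with 1 point per cell class and library with 20 or more cells. The classes lay between 1.12 and 4.72 in the day 5 libraries and between 18.04 and 22.1 in the day 14 libraries.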

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

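Of the tests given here, those on mixed cells, on background RNA, on Spp1 transcription, on the copy ratio across classes and on the sort gate were chosen only after the result was seen.

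Microglia and monocytes or macrophages differed in their change over time. The difference of the day effects passed for 218 genes. It was higher in microglia for Itgax (3.61), Lpl (2.43), Cxcl2 (2.23), Fn1 (2.21) and Bhlhe40 (2.20). It was lower in microglia for Lgals1 (-2.32), Mthfd2 (-2.09), F13a1 (-2.08), Cd5l (-2.08), Wfdc17 (-2.07) and Spp1 (-1.11). These genes stand here because a test of the difference between 2 classes passed. The count was 135 without day 5 replicate 1, F13a1 had an adjusted p of 0.413 without day 14 replicate 1, and Cd5l had 0.176 without day 14 replicate 2. No technical explanation was tested for these genes, and changes in the make-up of each class stay open beside a change within cells.

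Some cells took part in none of the gene comparisons. Unnamed cluster 6 (338 cells), whose best-scoring type was microglia, was led by Cst7, Spp1, Apoc1, Fabp5 and Gpnmb. Cluster 14 (148 cells) was led by the proliferation genes Hist1h2ap, Pclaf and Stmn1. Cluster 2 (193 cells) was led by Cx3cr1, Sparc and Olfml3, and 72.7% of its cells had a high doublet score. A further 648 cells were left out by the rule for mixed cells. Outside the lymphocyte classes that rule asked only for T or B cell UMIs, not for phagocyte RNA. In cluster 14, whose best-scoring type was T cell, it removed 4 of 46 and 2 of 59 cells on day 5. On day 14 it removed 19 of 39 and 20 of 49 there, so T cells may be among the cells left out.

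The Spp1 UMIs of the T cell clusters were weighed first. Mixed cells held 86.9% of them (4537, against 686 in the T cells kept) and 33.6% of all UMIs of these clusters, which is consistent with phagocyte RNA in those droplets. In the T cells kept, Spp1 CPM of Foxp3-positive cells on day 14 was 0.812 times that of B cells (95% interval 0.611 to 1.08). It was 1.09 times that of NK cells (0.833 to 1.41), and by CPM both are levels that background RNA could give. Per cell, Foxp3-positive cells held 0.756 and 1.36 Spp1 UMIs, against 0.509 and 0.694 in B cells and 0.347 and 0.8125 in NK cells. Background RNA at an equal amount per droplet is thus not settled by the CPM ratios. A higher Spp1 part of all RNA in Foxp3-positive than in other CD4 T cells is argued against by a difference of -0.99 ± 0.31 in CPM. That difference did not pass in edgeR (adjusted p 0.0738). Per cell the 2 sets were close on day 14, at 0.756 and 1.36 Spp1 UMIs against 0.722 and 1.45. The CPM difference therefore does not decide on transcription per cell. Low Spp1 expression in T cells stays open, since other CD4 T cells held 1.54 times the B cell level (1.19 to 1.98), and so does phagocyte RNA left in them, since a sub-cluster of 93 kept cells was led by genes that include Spp1, C1qa and C1qc.

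Gene copies that rose in every class where they were tested were weighed next. Among genes with shared 3' ends 17.6% rose in every class, against 0.900% of the others, which is consistent with reads that fit several copies being assigned differently in the 2 sets of matrices. A rise of Ftl1-ps1 by its own transcription is argued against, since its highest class ratio to Ftl1 was at most 1.17 times the lowest in the day 14 libraries (chi-square p 0.917 and 0.120 across classes), but in day 5 replicate 1 the ratios differed 4.21 times (p 2.24e-05), so some transcription of it on day 5 stays open. For Psme2b the 2 explanations cannot be told apart, at 2.29 times, with a chi-square p of 0.358 and 0.357 in the day 14 libraries and few UMIs. Upstream processing and day are confounded, since the matrix headers differ, and genes without shared ends that rose in every class (30) stay open, and interferon-induced genes such as Usp18 and Slfn5 are among the genes that rose.

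The higher share of T cells and the lower share of microglia on day 14 were weighed last. With the highest library floor applied to all cells, the differences were 16.5 percentage points for T cells and -31.2 for microglia, so the lower floor of the day 5 libraries is argued against for both. A gate that let in more microglia on day 5 is argued against for T cells, whose share among cells other than microglia was 8.58 times as high on day 14. For microglia that gate and a loss of cells cannot be told apart: border-associated macrophages, the other resident class, fell to 0.0960 of their day 5 share among cells other than microglia, and the labels give only a gate on high CD45. A biological change between the days stays open and untested.

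For Foxp3-positive against other CD4 T cells, 3 of the 32 splits that keep the library block gave as many genes as the real 53, the real split included, and the highest other split gave 67, so chance is not excluded. Of the 8 splits that part every pair, the real one gave the most genes, with 47 in the next.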

How the results depend on the processing

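The tests with Scrublet calls alone, the highest library floor, high doublet scores left out, cluster 2 counted as microglia, shared 3' ends left out, an innate-like sub-cluster left out of T cells and, for Foxp3-positive cells, the day 14 libraries alone or doublets kept were chosen only after the result was seen. In all, 3016 alternative values of 235 results were computed: 2587 were labelled the same, 367 weaker, 47 stronger and 15 reversed. For named genes, lists and Spp1, the same means that direction and side of the threshold were kept. Weaker then means short of the threshold, and stronger newly past it. For counts of genes or lists, weaker and stronger mean a count that fell or rose beyond a fixed factor. For shares, the same means the same sign, and stronger a call in edgeR on cells per class. Named genes kept direction and side of the threshold in 1856 of 2000 values and lists in 401 of 592. The comparisons, which are counts, shares and Spp1, were labelled the same in 330 of 424, and all 47 stronger labels were among them. A gene no longer tested in a setting gives no value there. The cause was not tested for any change below except where a cause is given.

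Doublet handling changed the T and B cell counts most. With Scrublet calls alone, the handling first intended, T cells had 712 changed genes (224 higher, 488 lower) in place of 32 and B cells 306 (151 higher, 155 lower) in place of 35, and Spp1 was -2.10 in B cells and -0.33 in NK cells. Ccl5 in T cells was 0.13 in place of -0.86. With all doublets kept the counts were 712 in T cells and 313 in B cells, Spp1 was -2.10 in B cells and -1.05 in NK cells, Ccl5 in T cells was 0.13, and Foxp3-positive against other CD4 T cells gave 11 genes. With high doublet scores left out B cells had 124 genes and plasmacytoid dendritic cells 31 (27 higher, 4 lower), and Spp1 was 1.42 in B cells, -0.072 in neutrophils and 0.047 in plasmacytoid dendritic cells.

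DESeq2 called 105 genes in B cells, 156 in NK cells, 670 in dendritic cells, 158 in microglia, 466 in monocytes or macrophages, 291 in neutrophils, 45 (23 higher, 22 lower) in plasmacytoid dendritic cells and 7 for Foxp3-positive cells, and Spp1 in dendritic cells was -1.16, short of the threshold. In B cells it moved the median of all genes by 0.104. Without a filter on low counts B cells had 221 genes, T cells 132, microglia 595 and plasmacytoid dendritic cells 224. Thinning left 186 genes in NK cells, 18 in T cells, 160 in microglia and 62 in plasmacytoid dendritic cells, where fewer UMIs were used. The highest library floor left 14 genes in B cells and 95 in NK cells. B cells had 62 genes at a mitochondrial limit of 5% and 66 at 1000 UMIs per cell. Leaving out genes with shared 3' ends gave 1 gene in B cells, 12 in T cells and 67 in plasmacytoid dendritic cells. In B cells 0 lower genes were called in place of 4, and in T cells 3 in place of 5. Fam129c, Vpreb3 and Btg2, named lower genes of B cells, had 29.7%, 0% and 0% shared windows. They were below the limit and not left out, so removal of called genes does not account for all lost calls. At Leiden resolution 2 Spp1 in neutrophils was -0.90. Leaving the innate-like sub-cluster out of T cells gave 18 genes there, with Cx3cr1, Dusp2, Hspa1a and Ltb short of the threshold. Counting cluster 2 as microglia gave 372 genes for the difference of day effects.

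With the replicate number as a block, B cells had 71 genes, T cells 69 and plasmacytoid dendritic cells 35 (19 higher, 16 lower, in place of 35 and 66), and Spp1 in B cells was 1.46. Residuals of libraries with the same number correlated between -0.20 and 0.04 across genes in the 8 classes, so the numbers gave no sign of pairing. By edgeR on cells per class, log2 changes in share were 3.65 for T cells, 3.43 for gamma delta T or innate lymphoid cells, 1.52 for NK cells, 1.47 for B cells, -3.18 for microglia, -2.79 for border-associated macrophages and -1.22 for neutrophils, all past the threshold, which the exact test cannot reach. With the block they were 3.60, 3.33, 1.53, 1.34, -3.21, -2.69 and -1.22, also all past it.

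For Foxp3-positive against other CD4 T cells the count was 7 without the library block, 337 against all Foxp3-negative T cells and 336 in the day 14 libraries alone. Of the 74 lists called by camera, an estimated correlation left 0 (9 of all 185 tests at an unadjusted p under 0.05). Fry called 16 lists, 14 of them among those 74.

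Leaving out 1 library at a time gave ranges, with the lone library of a day assumed to vary like the other day's. Spp1 lay between 1.41 and 1.63 in B cells, -0.070 and 0.64 in NK cells, -0.14 and 1.35 in T cells, 1.19 and 2.22 in monocytes or macrophages, -1.70 and -0.77 in dendritic cells, -0.38 and 1.52 in microglia, -0.98 and -0.58 in neutrophils, and -0.91 and 0.61 in plasmacytoid dendritic cells. The low ends in NK cells, T cells, monocytes or macrophages, dendritic cells and microglia came without day 14 replicate 2, the -0.58 without day 14 replicate 1, and the 0.61 without day 5 replicate 2. Gene counts lay between 0 (without day 14 replicate 1; 218 at an unadjusted p under 0.05 in edgeR) and 113 (without day 14 replicate 2) in B cells, 163 (without day 5 replicate 1) and 295 in NK cells, 36 and 85 (without day 5 replicate 1) in T cells, 688 (without day 14 replicate 2) and 1584 in dendritic cells, 215 (without day 5 replicate 1) and 522 in microglia, and 92 and 202 (without day 14 replicate 2) in plasmacytoid dendritic cells. They lay between 135 (without day 5 replicate 1) and 278 for the difference of day effects. For Foxp3-positive cells they lay between 0 (without day 14 replicate 2, 173 genes tested and 2 at an unadjusted p under 0.05 in edgeR) and 181 (without day 5 replicate 1). Differences in share lay between -2.62 and 7.51 percentage points in dendritic cells, -4.79 and 10.5 in monocytes or macrophages (both low ends without day 14 replicate 2), -0.162 (without day 14 replicate 1) and 0.933 in plasmacytoid dendritic cells, 1.55 and 6.89 in B cells, 3.97 and 10.5 in gamma delta T or innate lymphoid cells, and -5.52 and -2.16 in border-associated macrophages.

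Of 131 named gene results, 44 had no call without at least 1 library, 28 by falling short of the threshold and 25 by no longer being tested, with some in both sets. They were 20 of 20 for Foxp3-positive cells, 8 of 8 in B cells, 5 of 13 in T cells, 6 of 10 in plasmacytoid dendritic cells, 2 of 10 for the difference of day effects, 1 of 10 in dendritic cells, 1 of 10 in neutrophils (Orm1) and 1 of 20 in microglia (Gpx3).

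Recovery in simulated counts was lowest in T cells among the 8 classes, at 17% of 2-fold and 54% of 4-fold changes, against 74% and 95% in dendritic cells.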

Other observations

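No further tests were run for this part, so none of its tests were chosen after the result was seen; its values were read after clustering. The T cells split into sub-clusters that the class comparison sums over. Cells led by NK receptor genes, Xcl1, Trdc and Fcer1g, with no T cell marker among the leading genes, were the largest, with 7 and 3 cells on day 5 and 108 and 60 on day 14. CD8 cells led by Gzmk numbered 6 and 6 on day 5 and 98 and 36 on day 14, and cells with Cd40lg and Cxcr6 numbered 3 and 5 and then 64 and 45. Cells with Klf2 and S1pr1 numbered 6 and 4 and then 78 and 27. An interferon sub-cluster led by Ifit3, Ifit1 and Cxcl10 held 1 and 1 cells on day 5 and 36 and 32 on day 14. A cycling one held 0 and 0 and then 19 and 17, and the day 5 count of 0 is of 36 and 44 T cells. A sub-cluster of 8 and 10 cells on day 5 and 44 and 31 on day 14 was led by Gzma, the MHC class II genes Cd74, H2-Eb1 and H2-Aa, and Spp1, Ly86, C1qa and C1qc, so phagocyte genes remained in T cells after mixed cells were left out. The sub-cluster led by Areg, Ctla4 and Foxp3 numbered 4 and 5 and then 55 and 37. Cells with Ccr7 and Lef1 numbered 1 and 10 on day 5 and 13 and 1 on day 14.

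The dendritic cells of day 14 held a larger part of cluster 16, at 46.2% against 15.6%. They also held a larger part of cells with Xcr1, at 31.4% against 8.47%, and of cells with Ccr7, at 19.2% against 7.13%. Cluster 6, with the highest Spp1, held 76 and 78 cells on day 5 and 115 and 69 on day 14. Microglial cluster 3 made up 47.5% of microglia on day 5 and 87.1% on day 14.

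Markers of oligodendrocytes, the myelin-forming cells, gave 102 and 108 CPM over all cells on day 5 and 162 and 154 on day 14. Markers of ependymal or choroid plexus cells gave 23.2 and 125 CPM on day 5 and 1.81 and 105 on day 14, so the libraries of 1 day differed more than the days did. The values are those of all cells used and give no source for this RNA.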
